A study of Homo sapiens with 30 samples.

How the data were processed

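RNA of A375 cells was hybridized as biotin-labelled cRNA to 30 Affymetrix HG-U133 Plus 2.0 arrays, 3 for each of 10 groups: 0.065% DMSO or 650 nM MLN4924 for 1, 2, 4, 8 or 24 h. Groups, times and replicate numbers were taken from the sample titles. All 30 arrays were used. The deposited table gives 1 value per probe set and array for 54675 probe sets, and the unit of the deposited values is intensity, a linear probe set signal to 1 decimal. The submitters' processing notes name Affymetrix Expression Console for this step. Its version and algorithm are not given in the sources used here. The values ran from 0 to 18206.6, 55 of them were 0, and the mean after trimming 2% at each end was 150.02 on every array, so the authors' processing scaled the arrays to a common trimmed mean. The distributions were not otherwise equal. No raw image data and no detection calls were used here.

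Probe sets were matched to genes by the symbols supplied with the table: 41097 had 1 symbol, 1801 several and 11777 none. The table includes 62 control probe sets, and any of them with 1 symbol were kept. Of all probe sets with 1 symbol, 41043 had a gene identifier found in a table of gene names. Signals were quantile-normalized between arrays and transformed as log2(signal + 32). For each gene the probe set with 1 symbol and the highest mean over all arrays was kept, which gave 19775 genes. The 3 arrays per group limit the precision, and genes near the background (the median normalized signal was 36.58, a log2 value of 6.1) have their changes compressed by the added 32.

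The model was fitted with limma 3.58.1 in R 4.3.3 as 1 mean per group over all 30 arrays (20 residual degrees of freedom, prior degrees of freedom 3.037), followed by eBayes. Contrasts were MLN4924 minus DMSO at each of the 5 times, their mean, the 4 differences between consecutive times, and DMSO 24 h minus 1 h. An F test of the 5 effects asked whether a gene differed at any time. Adjusted p-values are Benjamini-Hochberg per contrast, and genes were called at an adjusted p under 0.05. Tests are two-sided. Replicate numbers were not used as pairs.

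Before the data were examined, the groups, comparisons, tests, gene lists, the rule for named genes and the main alternatives were fixed. The 28 gene lists (680 memberships, 607 of them measured, the rest not analysed here) cover the drug pathway, targets of NRF2, p53, NF-kB, HIF, ATF4, MYC (with ribosome biogenesis), SRF with YAP, and interferon, outputs of the MAPK pathway, immediate early and AP-1 genes, and G1/S, G2/M and histone genes. They further cover the unfolded protein response, heat shock, proteasome subunits, cholesterol synthesis, ribosomal proteins, the BCL2 family, DNA repair, senescence-associated secretion, the melanocyte lineage, housekeeping genes and markers of fibroblasts, epithelial and keratinocyte cells, blood and endothelium. Lists were drawn up from general knowledge, some genes are on more than 1 list, and none was chosen on these samples. Each was tested with camera (preset correlation 0.01) against all other genes, with Benjamini-Hochberg over the 140 tests of 28 lists at 5 times, or over 28 lists for the other contrasts, and again with an estimated correlation. The list tests on DMSO 24 h minus 1 h were an exception to the fixed plan and were chosen after the data were seen. A list's median is over its measured members, and "adjusted over the list alone" is Benjamini-Hochberg over its members in that contrast.

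The rule for named genes took, for each MLN4924 comparison, the 10 largest increases and 10 largest decreases among called genes whose 3 treated arrays lay on one side of the 3 DMSO arrays and whose higher group mean was above the median of all values. It added up to 4 called members per list and 34 genes set in advance, and 5 increases and 5 decreases for the changes between times and for DMSO. Of this set the report prints those with the largest change and mainly those whose call did not rest on a single array. Values under other settings are part of the closing section. UBE2F at 8 h, CBR3 and NUSAP1 at 24 h and the list members named among the other observations were chosen after their values were seen. Gene symbols of clones and open reading frames were passed over.

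The fit was tested on simulated data with the same groups, in which 200 of 19775 genes were changed at 24 h. Of genes changed by a log2 value of 0.5, 29 of 57 were called (50.9%), of those changed by 1, 68 of 73 (93.2%), and of those changed by 2, 70 of 70. Of the 177 calls 10 were false. Camera gave a p under 0.05 for 0 of 200 random lists of 25 genes, and a p of 2.72e-21 for a list raised by 0.3. The simulated genes varied independently of each other, so this does not test camera on lists whose members vary together.

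Arrays were checked for duplicates within each group (none, highest correlation 0.98968), but not between groups. They were also checked for the 3' to 5' signal ratio (ACTB 1.144 to 1.744, GAPDH 0.838 to 1.015) and for brightness. DMSO 2 h replicate 1 had the highest ratio of both genes and DMSO 2 h replicate 2 the next ACTB ratio (1.681). At 2 h the mean GAPDH ratio was 0.9598 in DMSO and 0.8999 with MLN4924 (exact permutation p 0.3). The deposited median signal was lower with MLN4924 than with DMSO at 1 h (35.3 against 37.67), 8 h (35.57 against 41.33) and 24 h (34.63 against 38.27), each with an exact permutation p of 0.1, the smallest that 3 against 3 arrays can give. Alternatives were: the replicate number as a fixed or random term, centring each array on its median, leaving out genes of low signal, every probe set on its own, the mean of a gene's probe sets, leaving out probe sets that can cross-hybridize (suffix _x_at or _s_at), eBayes with trend and robust, array weights, a fit of only the groups compared, adjustment over the 5 comparisons together, stricter thresholds, other added constants (1 and 128), fry in place of camera, and leaving out each array in turn. Chosen after seeing the data were: the signals as deposited, the brightness of each array as a covariate, leaving out the 3 arrays of lowest weight, leaving out DMSO 2 h replicates 1 and 2 together, and the added constants 1 and 128 for single genes. The values of single genes in the fits run for the counts were also read out only then. With these constants each gene kept its probe set. Under the other scalings the probe set was chosen again, which changed it for 14 genes, 0 of them named. Quantile normalization, planned as an alternative, became the main setting because the table is linear. Chance was examined by regrouping arrays, for the 6 arrays of a comparison in all 10 ways and otherwise within times in 100 ways. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.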

Results

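Gene expression was measured in A375, an established human melanoma cell line with an activating BRAF mutation, after addition of MLN4924 or of the vehicle DMSO. MLN4924 (pevonedistat) inhibits the NEDD8-activating enzyme, a heterodimer of NAE1 and UBA3 that starts the attachment of the ubiquitin-like protein NEDD8 to cullins. Cullin-RING ubiquitin ligases need this modification to be fully active, and their known substrates include NRF2, CDT1, p27 and inhibitors of NF-kB. The series asks how transcript levels differ between cells given 650 nM MLN4924 and cells given DMSO at 1, 2, 4, 8 and 24 h. There were 3 arrays in each of the 10 groups, 30 in all, and each time had its own DMSO arrays. The labels do not state that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The median signal of an array lay between 32.6 and 44 and its mean between 225.2 and 261.3, in the scale of the deposited table. The number of arrays limits the precision of each value below.

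Each log2 change is a difference between group means of log2(signal + 32) with n = 3 arrays per group, its SE and its adjusted p come from limma, and genes are identified by symbol. Because of the added 32, changes of dim genes are understated. Counts of list members that rose or fell rest on the limma call and its sign alone. For every gene named as risen or fallen with MLN4924 at a given time, all 3 MLN4924 arrays lay on one side of all 3 DMSO arrays. Chance alone gives such a separation for 10% of genes. On the first principal component, which held 28.6% of the variance, the MLN4924 arrays of 24 h scored 47.56 to 50.38 and the DMSO arrays of 24 h scored -18.17 to -17.06. The MLN4924 arrays of 1 h, at -8.67 to -8.12, lay within the range of the DMSO arrays of 1 h.

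**Figure D1:**
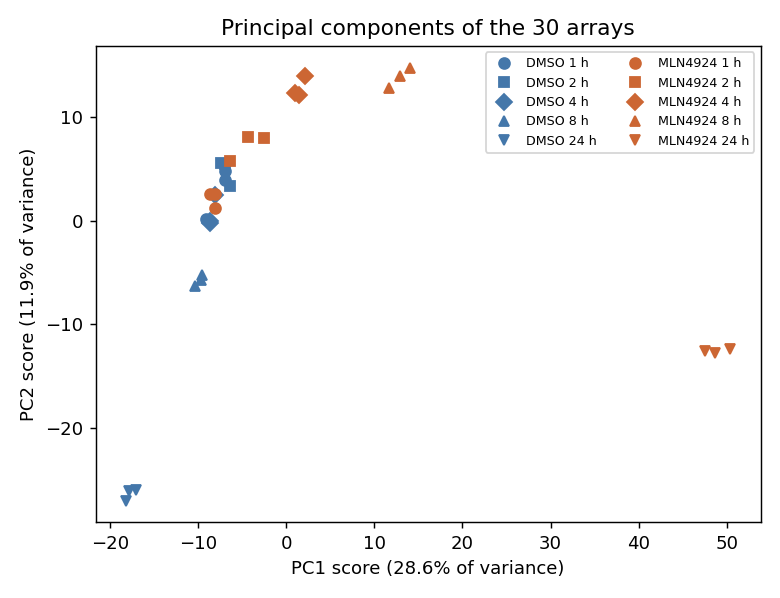
Scores of the 30 arrays on the first principal component (28.6% of the variance, horizontal) and the second (11.9%, vertical), coloured by treatment with a marker for each time. Along the horizontal axis the MLN4924 arrays move from -8.67 to -8.12 at 1 h to 47.56 to 50.38 at 24 h.

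At 1 h, CHAC1 rose with MLN4924. Its product degrades glutathione, and its gene is a target of the amino acid response factor ATF4. The signal of CHAC1 was 88.9 ± 12.1 (SD, n = 3) against 48.1 ± 3.66 in DMSO, a log2 change of 0.59 (SE 0.08, adjusted p = 0.0079 from limma). HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, had a log2 change of 0.55 (SE 0.10) that missed the threshold (adjusted p = 0.0586). As a group, the targets of ATF4 shifted upwards (22 measured, median log2 change 0.04, adjusted p = 0.000564), with 1 called over all genes and 2 when adjusted over the list alone.

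Of 19775 genes, 968 had an unadjusted limma p under 0.05 at 1 h, no more than the share of 0.05 that chance alone gives. CHAC1 was the only gene called. Its call ended without DMSO 1 h replicate 1 (adjusted p = 0.0559), DMSO replicate 2 (0.0532), MLN4924 1 h replicate 1 (0.0997) or MLN4924 replicate 2 (0.114), and with 1 instead of 32 added to the signal (0.097). It also ended in a fit of only the 6 arrays compared (0.648) and with the brightness of each array as a covariate (0.0521). Over its 20 alternatives the adjusted p ran from 1.42e-05 to 0.648. Camera also called 4 other lists at 1 h, none of which had a member called over all genes. These were targets of the hypoxia-inducible factors HIF (median 0.063, adjusted p = 0.0197), outputs of the MAPK pathway (0.039, 0.0183), immediate early and AP-1 genes (0.076, 0.0197) and, lower, proteasome subunits (-0.05, 0.0141). Adjusted over the list alone, 0 HIF targets, 2 MAPK outputs, 1 immediate early gene and 0 proteasome subunits passed. With an estimated correlation the adjusted p was 0.0994 for the MAPK list, 0.304 for the immediate early list and 0.312 for the proteasome list. All 4 calls rested on individual arrays. The HIF call was lost without DMSO 1 h replicate 1 (adjusted p = 0.202) and with genes of low signal left out (0.0709). The MAPK call was lost without DMSO replicate 2 (0.178) or MLN4924 replicate 2 (0.158), and with fry in place of camera (0.0555). The immediate early call was lost without DMSO replicate 2 (0.35), MLN4924 replicate 1 (0.0725) or MLN4924 replicate 2 (0.243), and with fry (0.222). The proteasome call was lost without DMSO replicate 1 (0.082), DMSO replicate 3 (0.189) or MLN4924 replicate 2 (0.069), and with each array centred on its median (0.914), signals as deposited (0.671), the mean of a gene's probe sets (0.188) or fry (0.151). Over 13 alternatives each, the adjusted p ran from 0.00288 to 0.202 for the HIF list, 0.000428 to 0.178 for the MAPK list, 0.00121 to 0.35 for the immediate early list and 0.00135 to 0.914 for the proteasome list.

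At 2 h, genes of the antioxidant response controlled by NRF2 rose. HMOX1 reached a signal of 1810 ± 140 (SD, n = 3) against 254 ± 25 in DMSO, a log2 change of 2.69 (SE 0.10, adjusted p = 5.81e-15). Other risers were OSGIN1, an oxidative stress response gene (1.42, SE 0.15, adjusted p = 4.28e-06), SLC7A11, the cystine transporter (0.98, SE 0.08, 2.38e-08), SRXN1, which encodes sulfiredoxin (0.89, SE 0.07, 4.65e-08), and TXNRD1, which encodes thioredoxin reductase (0.76, SE 0.06, 3.79e-08). The transcription factor gene MYC rose by 1.14 (SE 0.09, adjusted p = 3.79e-08) and CCN2, a matricellular protein gene induced by SRF and YAP, by 1.06 (SE 0.10, 5.59e-07). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose by 0.87 (SE 0.07, adjusted p = 2.38e-08). The immediate early gene EGR1 fell by 0.84 (SE 0.15, adjusted p = 0.0045).

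Of the 35 measured NRF2 targets, 9 rose, 0 fell and the rest did not pass (17 up and 0 down when adjusted over the list alone, list median 0.158, camera adjusted p = 3.41e-28). The ATF4 and amino acid response list followed with 6 of 22 up (9 adjusted over the list alone, median 0.156, adjusted p = 2.28e-13). CHAC1 rose by 1.34 (SE 0.08, adjusted p = 4.67e-10). Of the 24 HIF targets 2 rose (4 up and 1 down adjusted over the list alone, median 0.087, adjusted p = 0.000185), among them PDK1, which restrains mitochondrial pyruvate use (0.89, SE 0.08, 2.93e-07), and the vasodilator peptide gene ADM (0.46, SE 0.07, 0.000403). The 37 genes of the G1/S transition and DNA replication shifted upwards (median 0.053, adjusted p = 0.000179) with 0 called over all genes by limma, and 2 when adjusted over the list alone.

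In all, 109 genes were called at 2 h, 67 up and 42 down, and 8 changed at least 2-fold, each upwards. The count depended on single arrays: it was 69 without DMSO 2 h replicate 1, 68 without DMSO replicate 2, 244 without DMSO replicate 3 and 71 without MLN4924 2 h replicate 2. Median centring gave 62 up and 26 down. A fit of only the 6 arrays compared called 10. Of the genes named above at 2 h it did not call SRXN1 (adjusted p = 0.146, range 2.11e-09 to 0.146 over 21 alternatives), TXNRD1 (0.127, range 4.69e-10 to 0.127), CCN2 (0.146, range 2.74e-08 to 0.146), PMAIP1 (0.127, range 6.21e-10 to 0.127 over 20), PDK1 (0.091, range 1.3e-08 to 0.091) or ADM (0.331, range 1.82e-05 to 0.331). Adjustment over the 5 comparisons together called 434, of which 184 were up and 250 down. The DMSO arrays of 2 h had a mean ACTB 3' to 5' signal ratio, a measure of RNA quality, of 1.563 against 1.286 with MLN4924 (exact permutation p = 0.2). Replicates 1 (1.744) and 2 (1.681) had the highest ratios of all arrays. Without both, an alternative chosen after seeing the data that leaves 1 DMSO array at 2 h, the count was 41, 27 up and 14 down. Of the genes named above at 2 h, EGR1 (adjusted p = 0.291, range 0.000234 to 0.291 over 20 alternatives) and ADM (0.188) then lost their call, and the others kept it. The log2 change of EGR1 went from -0.84 (SE 0.15) to -0.77 (SE 0.22) and that of ADM from 0.46 (SE 0.07) to 0.36 (SE 0.09). Both calls ended with a larger SE, from the fewer arrays left, and with a smaller change, only slightly so for EGR1. Other named genes at 2 h lost more of their change, such as MAP7D1 (-0.6 to -0.29) and ANKRD1 (0.65 to 0.41). The change of others grew, such as ID2 (-0.61 to -0.84) and CXCL1 (0.31 to 0.41). This fit therefore neither shows nor excludes RNA quality as a cause. Heat shock genes (14 measured, median 0.032, adjusted p = 0.0212, 1 up over all genes and adjusted over the list alone) and MYC targets with ribosome biogenesis genes (22 measured, median 0.048, adjusted p = 0.0361, 1 up, 2 adjusted over the list alone) were called but not with an estimated correlation, where the adjusted p = 0.052 and 0.0603. The heat shock call also ended without DMSO 2 h replicate 1 (0.0643), DMSO replicate 3 (0.0706) or MLN4924 replicate 2 (0.0721), with adjusted p from 0.00192 to 0.0721 over 14 alternatives. The call of the MYC target list ended without DMSO 2 h replicate 1 (0.0531), DMSO replicate 2 (0.121), MLN4924 replicate 2 (0.0567) or MLN4924 replicate 3 (0.087), and without DMSO replicates 1 and 2 together (0.402), with a range from 0.00192 to 0.402.

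**Figure D2:**
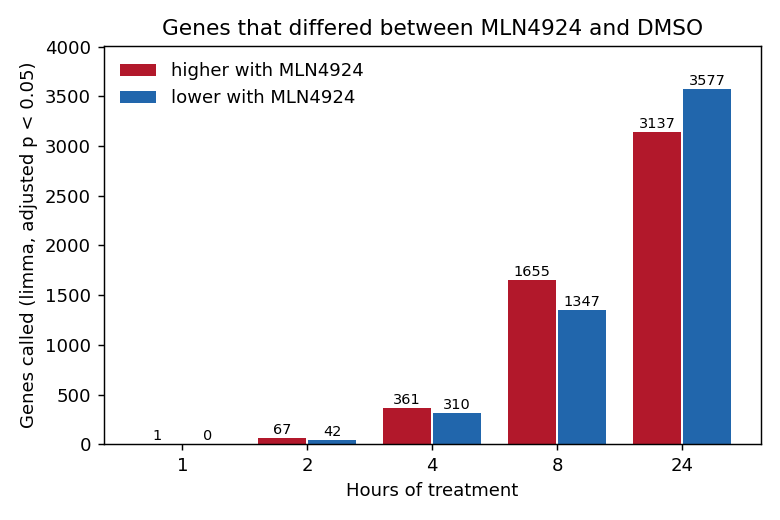
Number of genes called higher (up) and lower (down) with MLN4924 than with DMSO at each time, by limma at an adjusted p under 0.05 of 19775 genes, 3 arrays per group. The counts run from 1 up and 0 down at 1 h to 3137 up and 3577 down at 24 h.

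At 4 h, the antioxidant genes rose further while FOS and several other immediate early genes fell. HMOX1 had a log2 change of 3.97 (SE 0.10, adjusted p = 8.43e-19), with a signal of 3730 ± 115 against 208 ± 12.1 in DMSO (SD, n = 3). SRXN1 rose by 1.95 (SE 0.07, adjusted p = 8.47e-15) and SLC7A11 by 1.84 (SE 0.08, 5.56e-14). IL17RD, which encodes a membrane inhibitor of fibroblast growth factor signalling, rose by 2.20 (SE 0.16, adjusted p = 1.11e-09). The AP-1 gene FOS fell by 2.14 (SE 0.20, adjusted p = 9.69e-08), from 518 ± 34.6 in DMSO to 92.8 ± 11.5.

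Of the NRF2 targets 22 of 35 rose and 0 fell (26 up and 1 down adjusted over the list alone, median 0.371, camera adjusted p = 1.28e-48). Of the ATF4 targets 10 of 22 rose (14 up and 2 down adjusted over the list alone, median 0.334, adjusted p = 4.96e-18), such as the pseudokinase gene TRIB3 (1.00, adjusted p = 3.09e-11) and the stress response factor gene ATF3 (0.89, 5.86e-06). The call of ATF3 was lost without _x_at and _s_at probe sets, where another probe set stands for the gene. Of the HIF targets 5 rose (10 up and 2 down adjusted over the list alone, median 0.153, adjusted p = 1.24e-06), including ADM (1.16, 3.03e-11). Among the 37 G1/S genes 4 rose (9 adjusted over the list alone, median 0.069, adjusted p = 0.000162). They included CCNE1, the cyclin E1 gene (0.56, adjusted p = 0.000274). From other lists, EXO1, an exonuclease gene of the DNA repair list, rose too (0.59, adjusted p = 2.31e-05). So did DTL, a gene of the drug pathway list that encodes a substrate receptor of a cullin 4 ligase (0.39, 0.00298). A fit of only the 6 arrays compared did not call EXO1 (0.067, range 4.49e-06 to 0.067 over 20 alternatives) or DTL (0.113, range 2.45e-05 to 0.113 over 19). Of 22 genes controlled by SRF and YAP, 6 rose and 1 fell (the same counts adjusted over the list alone, median 0.027, adjusted p = 0.00114), with ANKRD1 at 1.64 (1.77e-09). Heat shock genes (2 of 14 up, also adjusted over the list alone, median 0.063, adjusted p = 0.00152) and MYC targets (1 of 22 up, 2 adjusted over the list alone, median 0.071, 0.00399) shifted upwards too.

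Among the 22 immediate early and AP-1 genes at 4 h, 10 fell and 5 rose (13 down and 5 up adjusted over the list alone, median -0.31, adjusted p = 0.000303). With an estimated correlation the list was not called (adjusted p = 0.0966, range 0.000196 to 0.0966 over 13 alternatives). Besides FOS, FOSB fell by 2.14 (adjusted p = 3.49e-05) and EGR1 by 1.87 (6.32e-09), while MYC rose by 1.57 (3.09e-11). Over the members that fell, the median treated level was lower at 4 h than at 1 h (-0.553), and the median DMSO level was higher (0.304). SPRY2, a feedback inhibitor of growth factor signalling, fell by 1.39 (SE 0.07, adjusted p = 3.74e-12), and DUSP10, a MAP kinase phosphatase gene, by 1.34 (SE 0.09, 1.8e-10). TFAP2B, a transcription factor gene, fell by 1.37 (SE 0.10, adjusted p = 1.49e-09), NR4A2, a nuclear receptor gene, by 1.45 (SE 0.12, 8.43e-09), and INHBA, an activin subunit gene, by 1.48 (SE 0.09, 6.53e-11).

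The total at 4 h was 671 genes, 361 up and 310 down, of which 51 changed at least 2-fold. With each array centred on its median the counts were 444 up and 212 down, 67.7% up instead of 53.8%, and a fit of only the 6 arrays compared called 295. With signals as deposited slightly more genes were down than up. BCL2 family genes (17 measured, 2 up, 3 up and 2 down adjusted over the list alone, median 0.116, adjusted p = 0.0317) had an adjusted p = 0.0607 with an estimated correlation. Their call was lost without DMSO 4 h replicate 1 (0.0809), DMSO replicate 3 (0.0747) or MLN4924 4 h replicate 2 (0.0713), with median centring (0.0517) and with genes of low signal left out (0.0769), with a range from 5.56e-05 to 0.0809 over 13 alternatives. Histone genes (22 measured, 2 down, 4 adjusted over the list alone, median -0.092, adjusted p = 0.0311) had an adjusted p = 0.176 with an estimated correlation. Their call was lost without DMSO 4 h replicate 2 (0.101), MLN4924 4 h replicate 1 (0.0913) or MLN4924 replicate 3 (0.0726), and with genes of low signal left out (0.0562), with a range from 0.00837 to 0.176. The p53 target list was not called at 4 h (4 up, 1 down, adjusted p = 0.982), and its median of -0.072 and its test differed in sign.

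At 8 h, targets of p53, cell cycle inhibitors among them, joined the genes that rose. GDF15, a stress cytokine gene, reached 381 ± 38.6 against 45.5 ± 5.54 in DMSO (SD, n = 3), a log2 change of 2.41 (SE 0.13, adjusted p = 2.03e-12). Its call was lost without _x_at and _s_at probe sets, where another probe set stands for the gene. CDKN1A, the gene of the cyclin-dependent kinase inhibitor p21, rose by 1.34 (SE 0.13, adjusted p = 7.34e-08), MDM2, the ubiquitin ligase of p53, by 1.32 (SE 0.10, 3.2e-10) and the growth arrest gene GADD45A by 1.51 (SE 0.10, 5.76e-11). HMOX1 stood at 3.81 (SE 0.10, adjusted p = 2.25e-18), ATF3 at 2.51 (SE 0.11, 4.79e-14) and ANKRD1 at 2.82 (SE 0.12, 4.79e-14). EGR1, lower at 4 h, was higher at 8 h by 1.32 (SE 0.15, adjusted p = 6.11e-07). TFAP2B fell by 2.41 (SE 0.10, adjusted p = 3.52e-14), the sulfate transporter gene SLC26A2 by 1.93 (SE 0.07, 9.13e-16), the activin antagonist gene FST by 1.81 (SE 0.08, 7.13e-14) and SOX10, a transcription factor gene of the melanocyte lineage, by 1.63 (SE 0.19, 7.98e-07).

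Of 32 measured p53 targets, 14 rose and 1 fell at 8 h (15 and 1 adjusted over the list alone, median 0.224, camera adjusted p = 1.03e-10). Of the NRF2 targets 27 of 35 rose and 0 fell, over all genes and adjusted over the list alone (median 0.598, adjusted p = 1.77e-31). KEAP1, which encodes the adaptor that presents NRF2 to a cullin 3 ligase, rose by 0.86 (SE 0.11, adjusted p = 5.6e-06). Among ATF4 targets 15 of 22 rose (17 adjusted over the list alone, median 0.488, adjusted p = 4.96e-18). Of the G1/S genes 17 of 37 rose (19 adjusted over the list alone, median 0.267, adjusted p = 3.2e-09), such as CCNE1 (0.92, 5.01e-08) and the CDK phosphatase gene CDC25A (0.88, 1.06e-06). EXO1 of the DNA repair list (1.16, 1.23e-10) and DTL of the drug pathway list (0.81, 3.37e-08) also rose. Genes of DNA damage repair and its checkpoints rose in 11 of 26 cases (12 up and 2 down adjusted over the list alone, median 0.145, adjusted p = 0.00405). HIF targets (9 up and 1 down of 24, 12 and 2 adjusted over the list alone, median 0.191, adjusted p = 3.96e-06), SRF and YAP targets (7 up and 1 down of 22, 8 and 1 adjusted over the list alone, median 0.227, 6.23e-06) and MYC targets (10 up of 22, 12 adjusted over the list alone, median 0.196, 3.36e-05) shifted upwards.

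The interferon response list shifted downwards at 8 h, with 6 of 29 down over all genes and adjusted over the list alone (median -0.082, adjusted p = 0.00423). Its members IFIT1 and IFI44, both induced by interferon, fell by 1.00 (SE 0.22, adjusted p = 0.00223) and 0.87 (SE 0.08, 5.88e-08). The call of IFI44 was lost without _x_at and _s_at probe sets, where another probe set stands for the gene. Genes of the unfolded protein response in the endoplasmic reticulum also shifted downwards, with 4 of 16 down (5 adjusted over the list alone, median -0.25, adjusted p = 0.00312). The drug pathway list, NEDD8 conjugation and cullin ligase genes, shifted upwards with 13 of 41 up and 1 down (14 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.0191). FBXW7, a substrate receptor of a cullin 1 ligase, rose by 0.47, and UBE2F, a NEDD8-conjugating enzyme gene, fell by 0.44 (its other probe sets changed by -0.33, -0.23 and 0.01). CDKN1B, the gene of p27, fell by 0.40 (adjusted p = 0.000299).

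The total at 8 h was 3002 genes, 1655 up and 1347 down, of which 164 changed at least 2-fold. Median centring gave 2796 up and 804 down (77.7% up instead of 55.1%), signals as deposited gave 1620 up and 1637 down, the brightness of each array as a covariate gave 1890 genes, and a fit of only the 6 arrays compared gave 1493. The unfolded protein response call was lost with median centring (adjusted p = 0.233) and with signals as deposited (0.134, range 1.61e-07 to 0.233 over 13 alternatives). The drug pathway call was lost with genes of low signal left out (0.0659, median 0.11) and with the mean of all probe sets of a gene (0.116, median 0.076, range 4.78e-08 to 0.116).

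**Figure D3:**
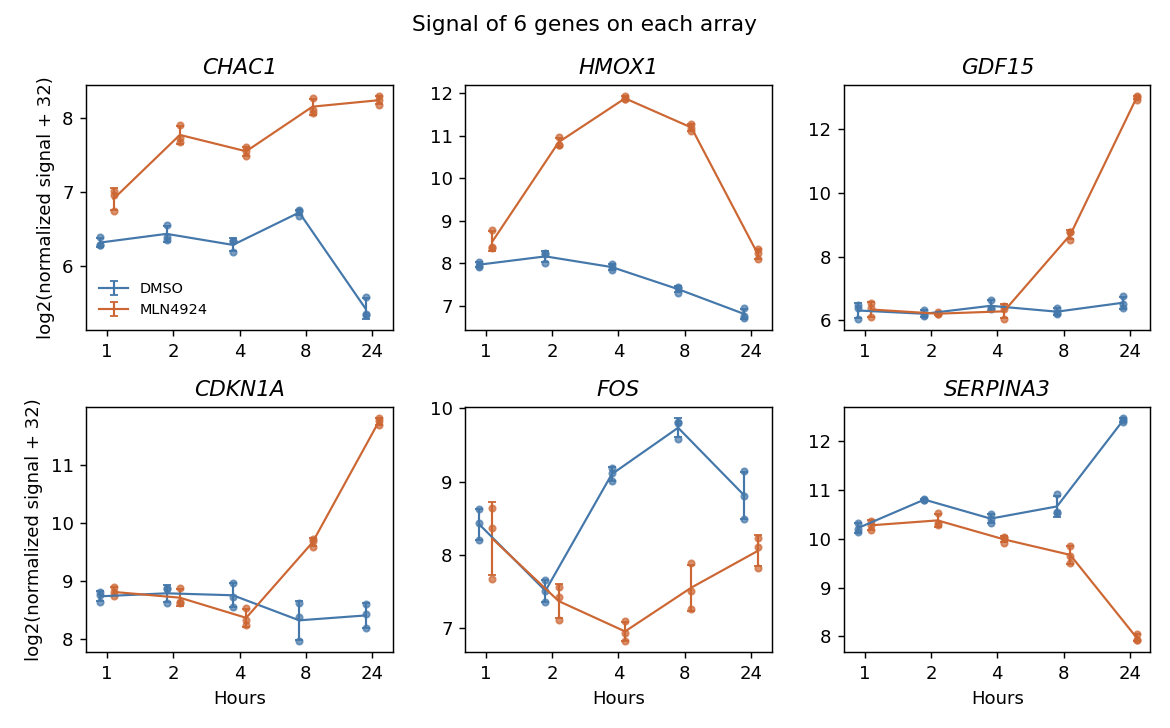
Normalized log2 signal in DMSO and in MLN4924 arrays, mean and SD, against time for selected genes, 3 arrays per group. The log2 change of HMOX1 with MLN4924 against DMSO was 3.97 at 4 h and 1.42 at 24 h. HMOX1 in DMSO was lower at 24 h than at 1 h. At 24 h that of GDF15 was 6.44 and that of CDKN1A 3.34.

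At 24 h, stress and p53 target genes stood far above their levels in DMSO and genes of mitosis far below. GDF15 had a signal of 8150 ± 281 against 62.6 ± 12.3 (SD, n = 3), a log2 change of 6.44 (SE 0.13, adjusted p = 5.57e-21). ATF3 rose by 4.98 (SE 0.11, adjusted p = 9.86e-21), GADD45A by 3.88 (SE 0.10, 1.57e-19), CDKN1A by 3.34 (SE 0.13, 7.41e-16) and MDM2 by 2.94 (SE 0.10, 1.54e-17). CCNB1, the cyclin B1 gene, fell by 1.84 (SE 0.06, adjusted p = 3.98e-18), from 2770 ± 41.9 to 753 ± 35.3. The acute phase gene SERPINA3 fell by 4.46 (SE 0.10, adjusted p = 9.86e-21), and TFAP2B fell by 4.51 (SE 0.10, 1.75e-20). S100B, a calcium-binding protein gene of melanocytic cells, fell by 3.49 (SE 0.15, adjusted p = 2.18e-15).

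Of 32 p53 targets 27 rose and 0 fell (28 and 0 adjusted over the list alone, median 1.282, camera adjusted p = 1.42e-24). They included BAX, a pro-apoptotic gene (1.01, adjusted p = 1.6e-07). SFN, a cell cycle inhibitor gene that is on the epithelial marker list and not on the p53 list, rose by 2.30. Of 33 genes of G2/M and mitosis 32 fell and 0 rose, over all genes and adjusted over the list alone (median -1.221, adjusted p = 3.95e-29). HMMR, a spindle protein gene, fell by 2.80 (SE 0.10, adjusted p = 2.31e-16) and KIF20A, a mitotic kinesin gene, by 2.34. The member that did not pass was NUSAP1 (-0.08, adjusted p = 0.444). The ATF4 targets showed 21 of 22 up, over all genes and adjusted over the list alone (median 1.332, adjusted p = 3.08e-21), with TRIB3 at 2.63 (SE 0.06, 1.31e-20), CHAC1 at 2.82 (3.14e-18) and the stress factor gene DDIT3 at 1.68 (4.31e-08). Among NRF2 targets 25 of 35 rose and 1 fell (26 and 1 adjusted over the list alone, median 0.465, adjusted p = 4.9e-12), with SRXN1 at 2.25 (1.7e-17) and HMOX1 at 1.42 (1.5e-11). For HMOX1 the DMSO arrays read 7.912 to 8.034 (log2) at 1 h and 6.711 to 6.932 at 24 h. The MLN4924 arrays read 8.355 to 8.779 at 1 h and 8.091 to 8.325 at 24 h. Its 24 h change thus rests on lower DMSO arrays, and not on treated arrays above those of 1 h. CBR3, a carbonyl reductase gene, fell by 1.33.

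MYC rose by 2.14 (SE 0.09, adjusted p = 2.69e-15), and 19 of 22 MYC targets and ribosome biogenesis genes rose at 24 h (20 up and 1 down adjusted over the list alone, median 0.662, adjusted p = 1.28e-11). PES1, needed to process ribosomal RNA, was higher by 1.36. Targets of SRF and YAP rose in 14 of 22 cases, over all genes and adjusted over the list alone (median 0.538, adjusted p = 3.2e-09), with ANKRD1 at 4.42 (6.87e-19), CCN2 at 2.97 (4.07e-17) and CCN1 at 2.80. Of the immediate early and AP-1 genes 12 rose and 4 fell (13 and 4 adjusted over the list alone, median 0.663, adjusted p = 8.7e-06). JUN, the partner of FOS in AP-1, rose by 1.68 (adjusted p = 3.72e-11). The G1/S genes went both ways, 17 up and 5 down of 37 by either adjustment, over all genes or adjusted over the list alone (median 0.178, adjusted p = 0.0129). Most G1/S genes fell in DMSO between 1 h and 24 h, as given below. A gene higher with MLN4924 at 24 h therefore need not have risen from 1 h. The replication licensing gene CDC6 rose by 1.17 (adjusted p = 3.57e-10), while MCM6, a subunit of the replicative helicase, fell by 0.76. DTL, which is on the drug pathway list, rose by 1.54 (adjusted p = 4.77e-14). The unfolded protein response list had 10 of 16 down and 2 up by either adjustment, over all genes or adjusted over the list alone (median -0.373, adjusted p = 0.0183), with the endoplasmic reticulum chaperone genes PDIA4 at -1.18 (5.83e-10) and HSP90B1 at -0.80. Interferon response genes were down in 9 of 29 cases and up in 1, also adjusted over the list alone (median -0.219, adjusted p = 0.0275), with ISG20 at -2.07 and IFIT1 at -1.49.

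UBA3, which encodes the catalytic subunit of the drug's target, fell by 0.61 (SE 0.15, adjusted p = 0.00181) at 24 h. The drug pathway list was not called at 24 h (14 up and 7 down of 41, adjusted p = 0.345). NFE2L2, the NRF2 gene, had a log2 change of 0.01 (adjusted p = 0.958), and CDT1 one of 0.18 (adjusted p = 0.618) and was called at no time. HIF1A rose by 0.23 and CDKN1B fell by 0.96. Camera did not call the other lists at 24 h. The adjusted p was 0.514 for HIF targets, 0.24 for MAPK outputs, 0.0523 for proteasome subunits, 0.0531 for the melanocyte lineage, 0.0645 for NF-kB targets, 0.112 for the BCL2 family and 0.56 for DNA repair. It was 0.477 for genes of senescence-associated secretion, 0.44 for heat shock genes, 0.501 for cholesterol synthesis, 0.502 for histone genes, 0.742 for ribosomal proteins and 0.608 for housekeeping genes. Markers of other cell types were not called either, with an adjusted p of 0.257 for fibroblast, 0.605 for epithelial, 0.527 for blood and 0.848 for endothelial genes. Of these lists, those of NF-kB targets, cholesterol synthesis, ribosomal proteins, senescence-associated secretion, the melanocyte lineage, housekeeping genes and the 4 other cell types were called by camera in none of the 5 MLN4924 comparisons as reported, but several were under other settings. Ribosomal proteins were called higher with arrays centred on their median and as deposited at 4 h (0.00246 and 0.000504, range 0.000504 to 0.996 over 13 alternatives), 8 h (0.00578 and 0.00119, range 0.00119 to 0.959) and 24 h (0.0282 and 0.0153, range 0.0153 to 0.826). Housekeeping genes were called higher in the same 2 ways at 4 h (0.0269 and 0.0132, range 0.0132 to 0.737) and 8 h (0.00898 and 0.00449, range 0.00155 to 0.644). At 24 h NF-kB targets were called higher with the mean of a gene's probe sets (0.0341) and without DMSO 24 h replicate 1 (0.0427) or replicate 3 (0.0435), with a range from 2.47e-09 to 0.139. The melanocyte list was called lower with both other scalings (0.026 and 0.0341) and the mean of a gene's probe sets (0.0341). It was also called without DMSO 24 h replicate 1 (0.0484), MLN4924 24 h replicate 1 (0.0364) or MLN4924 replicate 3 (0.0492), with a range from 7.49e-10 to 0.0826. Senescence-associated secretion was called higher at 2 h with genes of low signal left out (0.0465) and without DMSO 2 h replicates 1 and 2 (0.016), with a range from 0.016 to 0.731 over 14 alternatives. Fry, which does not compare a list with other genes, called all of these lists at 24 h except ribosomal proteins and endothelial markers. Proteasome subunits, called lower at 1 h, were called higher with both other scalings at 4 h (2.36e-05 and 5.04e-06, range 5.04e-06 to 0.486 over 13 alternatives) and 8 h (0.000202 and 0.000104, range 0.000104 to 0.895). They were also called higher at 4 h without DMSO 4 h replicate 3 (0.0498) or MLN4924 4 h replicate 1 (0.0364), and at 8 h with the mean of a gene's probe sets (0.0341). At 24 h they were called higher with both other scalings (0.00274 and 0.00154), the mean of a gene's probe sets (0.022), the replicate number as a fixed term (0.0485) and without MLN4924 24 h replicate 1 (0.0493), with a range from 0.000299 to 0.442.

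The 24 h comparison called 6714 genes, 3137 up and 3577 down, 34% of those tested, of which 1079 changed at least 2-fold. Median centring turned the split to 3584 up and 3050 down. The calls of the unfolded protein response (0.0769, median -0.373) and interferon response lists (0.0769, median -0.242) were lost when genes of low signal were left out, with adjusted p over 13 alternatives from 3.39e-11 to 0.0769 and from 3.63e-11 to 0.0769. The former was also lost with the other scalings (0.0641 and 0.0593). Over the 5 times, camera called 42 of 140 list tests, 34 up and 8 down, and 34 of these calls held with an estimated correlation. The 8 others are those given above with such an adjusted p.

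**Figure D4:**
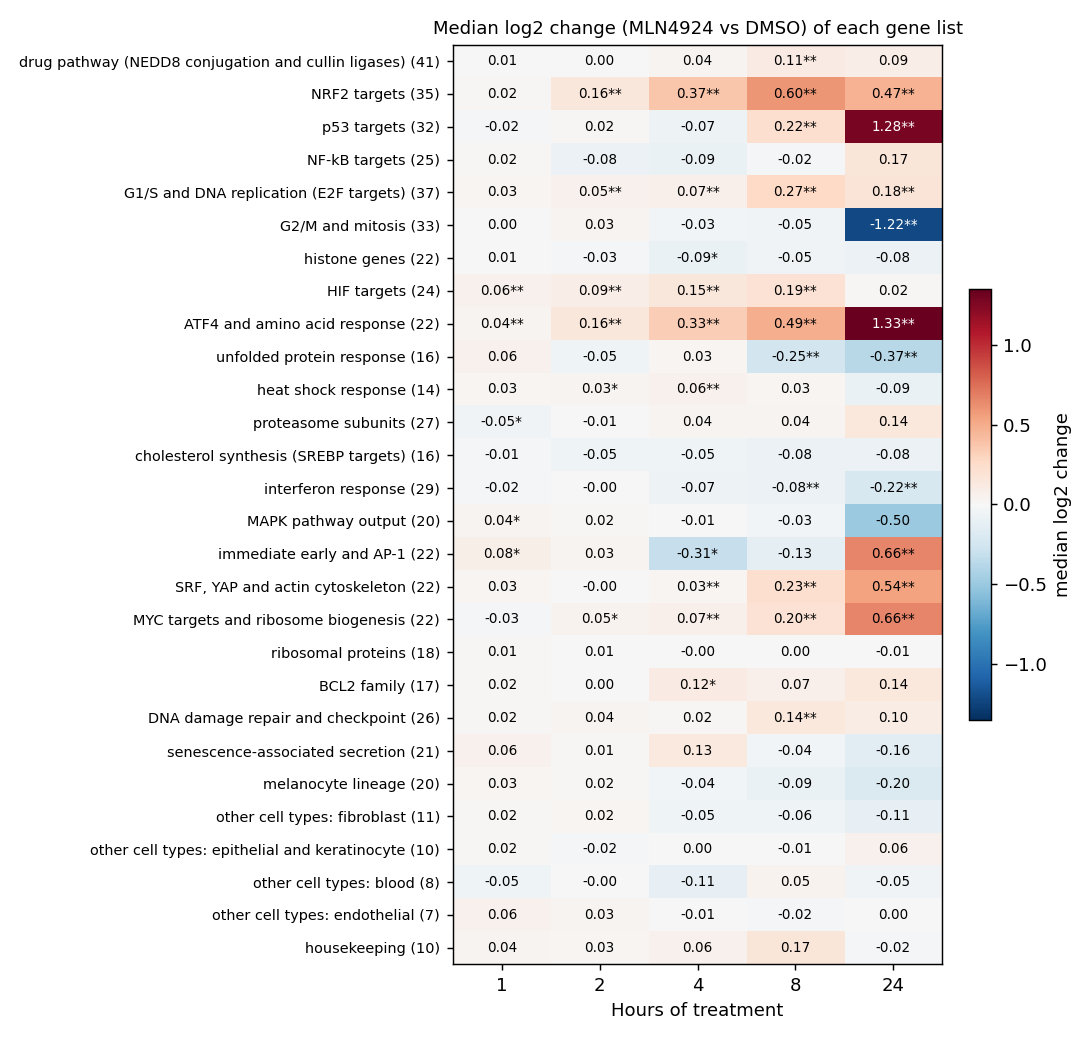
Median log2 change of the members of each of the 28 gene lists (vertical) at each time (horizontal), as colour. A star marks a list called by camera and a double star one that is also called with an estimated correlation, as for G2/M and mitosis at 24 h (-1.221) and p53 targets at 24 h (1.282).

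The change of the response to MLN4924 between consecutive times was tested for each list on its own, and no test compared 1 list with another. From 1 h to 2 h the NRF2 targets gained (median change 0.212, adjusted p = 1.19e-22, 8 called), led by HMOX1 at 2.14 (SE 0.14, 1.65e-09). From 2 h to 4 h they gained again (0.254, 9.01e-18, 5 called). In these steps the lists of p53 targets (adjusted p = 0.814 and 0.893) and of G2/M and mitosis (0.169 and 0.0601) were not called. The effect on FOS fell by 2.00 from 2 h to 4 h (SE 0.28, adjusted p = 0.000409). Most of this was a rise in DMSO, whose arrays read 7.366 to 7.666 (log2) at 2 h and 9.005 to 9.186 at 4 h. The MLN4924 arrays read 7.115 to 7.571 at 2 h and 6.836 to 7.098 at 4 h. From 4 h to 8 h the p53 targets gained (0.255, 1.99e-16, 9 called), with GDF15 at 2.59 (SE 0.18, 7.36e-09), while EGR1 turned by 3.20 (SE 0.21, 3.74e-09). The NRF2 targets also gained (0.116, 0.00627, 1 called), and the G2/M list was not called (adjusted p = 0.858). From 8 h to 24 h the p53 targets gained a median of 1.009 (2.2e-27, 25 called) and the G2/M genes changed by -1.171 (3.28e-39, 31 called). The effect on the NRF2 list did not pass that test (-0.034, 0.512). The number of genes whose effect changed was 29 (20 up and 9 down) from 1 h to 2 h, 97 (38 and 59) from 2 h to 4 h, 310 (153 and 157) from 4 h to 8 h and 3848 (1624 and 2224) from 8 h to 24 h. Leaving out 1 array moved some of these counts by more than 1.5 times. The count from 1 h to 2 h was 45 without DMSO 2 h replicate 3, and that from 2 h to 4 h was 61 without DMSO 2 h replicate 2. Without DMSO 2 h replicates 1 and 2 together these counts were 18 and 39. Median centring gave 32 up and 33 down from 2 h to 4 h. The count from 4 h to 8 h was 174 without DMSO 4 h replicate 3, 204 without DMSO 8 h replicate 1, 192 without MLN4924 4 h replicate 1 and 189 without MLN4924 8 h replicate 1. Median centring turned its split from 153 up and 157 down to 178 up and 78 down. A fit of only the groups compared called 1 gene from 1 h to 2 h, 23 from 2 h to 4 h, 117 from 4 h to 8 h and 3407 from 8 h to 24 h.

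Genes that MLN4924 changed at one time largely kept their direction at the next. Of the 8 h calls, 1030 genes were up at both 8 h and 24 h and 995 down at both, against 263 and 244 from independent draws, and 217 went opposite ways against 513. Between 4 h and 8 h, 293 genes were up at both times and 233 down at both, with 4 opposite, and between 2 h and 4 h, 55 and 23 with 0 opposite by limma calls. Genes are not independent of each other, so these expected numbers are a reference and no test. At any time, 6441 genes (32.6%) differed by limma's F test. The mean effect over the 5 times was called for 4975 genes, 2316 up and 2659 down. Median centring gave 3749 up and 1776 down, and the brightness of each array as a covariate gave 3116 genes. By that mean, 22 of 22 ATF4 targets rose (median 0.433, adjusted p = 3.81e-28), as did 23 p53 targets (0.263, 1.82e-19), while 27 G2/M genes fell (-0.264, 4.88e-20). Of the NRF2 targets 27 rose and 2 fell (0.297, 1.49e-28). A mean over the 5 times does not show an effect at each of them. The p53 and G2/M lists changed most between 8 h and 24 h, so their means lean on 24 h.

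In DMSO alone, genes also differed between 24 h and 1 h, which measures the change with time in culture without the drug. LOXL4, a lysyl oxidase gene, rose by 2.61 (SE 0.07, adjusted p = 4.83e-18), SERPINA3 by 2.21 (SE 0.10, 1.51e-13) and S100B by 1.87. CCN2 fell by 1.75 (SE 0.10, adjusted p = 4.71e-11), the amino acid transporter gene SLC7A5 by 1.61 (SE 0.12) and DKK1, a WNT inhibitor gene, by 1.59 (SE 0.05, 1.01e-15). Of the 37 G1/S genes 33 fell (35 adjusted over the list alone, median -0.458, adjusted p = 2.85e-27), as did 15 of 33 G2/M genes (19 adjusted over the list alone, -0.24, 4.07e-09) and 13 of 27 proteasome subunits (17 adjusted over the list alone, -0.236, 4.03e-10). ATF4 targets had 14 down and 1 up (15 and 1 adjusted over the list alone, -0.456, 4.29e-12). MYC targets had 14 down and 1 up (17 and 1 adjusted over the list alone, -0.362, 4.03e-10). The G1/S, ATF4 and MYC lists were higher with MLN4924 than with DMSO at 24 h, and part of that may be this fall in DMSO. These lists were not tested in treated arrays over time. Genes of cholesterol synthesis (4 of 16 up and 0 down, median 0.136, adjusted p = 0.00658) and of the melanocyte lineage (6 of 20 up and 1 down, 0.153, 0.0206) were higher, with the same counts adjusted over the list alone. The MAPK outputs (11 up and 5 down of 20, 12 and 6 adjusted over the list alone, 0.333, adjusted p = 0.0206) had an adjusted p = 0.0817 with an estimated correlation. The fibroblast markers (2 up and 0 down of 11, also adjusted over the list alone, 0.2, adjusted p = 0.0491) had an adjusted p = 0.0617 with an estimated correlation. In all, 3634 genes were called, 1959 up and 1675 down, of which 114 changed at least 2-fold. Of 28 lists 14 were called, 4 up and 10 down, and 10 held with an estimated correlation. These list tests in DMSO alone were chosen after the data were seen.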

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

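Some tests were chosen only after the results were seen. These are both tests on the immediate early genes and the comparison of treated arrays between 24 h and 1 h with the DMSO arrays. The list tests in DMSO alone and the repeats without 1 array on the signals as deposited were also chosen then.

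The effect of MLN4924 differed between consecutive times, by limma's test of the difference itself, for 29 genes from 1 h to 2 h, 97 from 2 h to 4 h, 310 from 4 h to 8 h and 3848 from 8 h to 24 h. The differences below are log2 values with 3 arrays per group. From 1 h to 2 h the effect grew for the antioxidant genes HMOX1 (2.14, adjusted p = 1.65e-09), OSGIN1 (1.25) and SLC7A11 (0.95), and for NMRAL2P (1.06) and TRIM16 (0.96). It changed downwards for EGR1 (-1.37), DPY19L2P2 (-0.77), LOXL4 (-0.72), RSRP1 (-0.56) and INTS6 (-0.51). From 2 h to 4 h it rose for IL17RD (1.66), HMOX1 (1.29), SRXN1 (1.06), EVA1C (1.02) and ANKRD1 (0.99). It fell for FOS (-2.00), NR4A2 (-1.39), EGR3 (-1.38), MANSC1 (-1.10) and ST8SIA4 (-1.04). From 4 h to 8 h it rose for EGR1 (3.20, adjusted p = 3.74e-09), the stress and arrest genes GDF15 (2.59), CDKN1A (1.73) and ATF3 (1.63), and ENTPD3 (1.53). It fell for CDKN1C (-1.66), CEMIP (-1.50), NFATC2 (-1.32), ART3 (-1.30) and SLC26A2 (-1.26). From 8 h to 24 h it rose for GDF15 (4.03, adjusted p = 9.76e-14), the cytokine gene IL24 (3.68), PLCXD2 (2.91), SUGCT (2.73) and ATF3 (2.47). It fell for SPRY4-IT1 (-3.63), SERPINA3 (-3.47), IGFBP5 (-3.34), HAPLN1 (-2.97) and IL17RD (-2.76).

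Of these 40 differences, 7 lost their call when 1 of the 12 arrays involved was left out. That of DPY19L2P2 was lost in 9 such repeats (highest adjusted p = 0.142), all except those without DMSO 1 h replicate 2, DMSO 2 h replicate 3 or MLN4924 1 h replicate 2. The call of INTS6 was lost in 8 (0.106), all except those without DMSO 1 h replicate 2, DMSO 2 h replicate 3, MLN4924 1 h replicate 1 or MLN4924 2 h replicate 3. For RSRP1 it was lost in 6 (0.0832), without DMSO 1 h replicate 1 or 2, DMSO 2 h replicate 1, MLN4924 1 h replicate 1 or 2, or MLN4924 2 h replicate 1. For EGR3 it was lost in 10 (0.138), all except those without DMSO 4 h replicate 3 or MLN4924 2 h replicate 2. For EVA1C it was lost in 8 (0.118), all except those without DMSO 2 h replicate 3, DMSO 4 h replicate 2, MLN4924 2 h replicate 3 or MLN4924 4 h replicate 2. The call of ST8SIA4 was lost in 4, without DMSO 2 h replicate 2 (0.07), DMSO 4 h replicate 2 (0.0521), MLN4924 2 h replicate 1 (0.0508) or MLN4924 4 h replicate 2 (0.0678). For ENTPD3 it was lost in 9 (0.0908), all except those without replicate 3 of DMSO 4 h, MLN4924 4 h or MLN4924 8 h. The call of LOXL4 was lost only with the mean of all its probe sets, among the settings run (0.923, range 7.73e-05 to 0.923 over 19 alternatives). Leaving out DMSO 2 h replicates 1 and 2, the arrays with the highest ACTB 3' to 5' ratios, was a setting chosen after seeing the data. It leaves 1 DMSO array at 2 h. Some changes stayed about as large, such as EGR1 (-1.37 to -1.29), RSRP1 (-0.56 to -0.57) and EGR3 (-1.38 to -1.36). Others shrank more, such as TRIM16 (0.96 to 0.75), INTS6 (-0.51 to -0.36) and EVA1C (1.02 to 0.78). The losses therefore neither show nor exclude RNA quality as a cause. In this setting more calls that use DMSO 2 h were lost. From 1 h to 2 h these were TRIM16 (adjusted p = 0.241, range 0.00264 to 0.241 over 19 alternatives), EGR1 (0.0816, range 2.49e-05 to 0.0816), DPY19L2P2 (0.413, range 0.027 to 0.413), INTS6 (0.532, range 0.00445 to 0.532) and RSRP1 (0.17, range 0.00638 to 0.995). From 2 h to 4 h these were EGR3 (0.261, range 0.0112 to 0.261), EVA1C (0.427, range 0.0148 to 0.427) and ST8SIA4 (0.263, range 3.55e-05 to 0.263).

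Other groupings of the arrays tested whether such counts arise by chance. For the comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 1 and 0 at 1 h, 109 and 3 at 2 h, 671 and 1 at 4 h, 3002 and 0 at 8 h, 6714 and 1 at 24 h, and 3634 and 1 for DMSO 24 h against 1 h. With treatment labels exchanged within times, 1 of 100 splits, the real one, reached the 6441 genes of the F test (highest other 6389), the 4975 of the mean effect (2324), the 29 from 1 h to 2 h (2) and the 310 from 4 h to 8 h (271). These shares are under 0.05, which argues against chance for the F test and the mean effect. Such splits test for no effect at any time. Splits that leave the groups of 1 time whole carry its real effect, so they cannot show whether the effect changed between times. Among splits that mixed the 24 h groups, the highest count was 409 for the F test and 186 for the mean effect. For the 97 genes from 2 h to 4 h, 3 of 100 splits gave as many, the real one included, also a share under 0.05. The highest other gave 196, more than the real count, so chance is not excluded there. For the 3848 genes from 8 h to 24 h, 9 of 100 splits gave as many (highest other 6566), so chance cannot be excluded by this test. The 8 other splits as large were among the 9 that kept the 24 h groups whole and mixed other times, and the highest of the rest was 237. The structure behind these counts is thus the difference between the 24 h groups.

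A pattern to weigh is the fall of immediate early genes at 4 h. Of 22 members 10 were lower with MLN4924 (FOS, FOSB, JUND, EGR1, EGR3, IER2, KLF4, KLF6, DUSP1 and NR4A1), with a median log2 change of -0.725. With 1 h as the reference, a rise of these genes in the DMSO cultures, for example from handling, is argued against as the whole cause. Their median in treated arrays changed by -0.553 (SE 0.0717) from 1 h to 4 h. That in DMSO arrays changed by 0.304, which accounts for part of the difference. By member, the treated change ran from -1.58 to -0.241 and the DMSO change from -0.143 to 0.821. By 2 h the treated median had already changed by -0.318 (SE 0.0757) and the DMSO median by -0.0143. The list was called higher with MLN4924 at 1 h, a call that rested on single arrays, so that reference may be raised. No test with 2 h as the reference was run. Scaling between arrays is argued against by a move of at most 0.0575 in their median under the other scalings (-0.667 and -0.726). An effect of the drug may remain as a hypothesis, but the members were picked for their 4 h difference, which uses the same 4 h arrays, and the call of the list was lost with an estimated correlation (adjusted p = 0.0966).

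Another is that the 24 h effect ran opposite to the change with culture time: across 19775 genes its r with DMSO 24 h minus 1 h was -0.511, but both share the DMSO 24 h arrays, and simulated data with no effect gave -0.5. The covariance was -0.0709 against -0.0111 in those simulations. That sharing alone is argued against by DMSO 8 h minus 1 h, which shares no array with the 24 h effect: r was -0.169 (rho -0.147), and -0.18 to -0.142 with each array left out, though genes are not independent replicates. Scaling as the whole cause is argued against by the signals as deposited. Dropping quantile normalization moved the 24 h effects by an SD of 0.0504 over genes and DMSO 8 h minus 1 h by 0.0458 (SD of these differences 0.498 and 0.174), and r stayed at -0.17, or -0.182 to -0.142 with each array left out, below the bound of -0.1 set in advance. Median centring adds no separate test, since a constant per array cannot change r. In treated arrays the 1959 genes higher in DMSO at 24 h had a median change from 1 h to 24 h of -0.0618 (SE 0.0159; DMSO 0.458), and the 1675 genes lower there had one of -0.0308 (DMSO -0.406). It may be that treated cultures did not go through the change that DMSO cultures went through, a hypothesis found and tested on the same data, and growth, density and medium were not measured.

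Probe sets without a single gene name, which the comparisons leave out, also differed at 24 h: 1838 of 13522 were called (13.6%), 962 higher and 876 lower with MLN4924.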

How the results depend on the processing

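Chosen after seeing the data were the signals as deposited, the brightness covariate, the fit without the 3 arrays of lowest weight, that without the 2 arrays of highest ACTB ratio and the other added constants for single genes. For the counts below, where no cause is named, the cause was not tested. With the replicate number as a fixed term the counts were 1, 102, 648, 2971 and 6693 at the 5 times, and with it as a random term 1, 109, 675, 3005 and 6717. The replicate numbers did not pair arrays: residuals of like numbers correlated at -0.106 to 0.073. Of 387 calls of named genes the fixed term kept 381 and lost 6, median centring kept 363 and lost 23, and signals as deposited kept 373 and lost 13. Of 42 list calls these kept 42, 38 and 39. They gained 1, 13 and 12 list calls. Besides those in the report, both scalings called the G1/S and unfolded protein response lists at 1 h, the drug pathway at 4 h and heat shock genes at 8 h, and centring the drug pathway at 1 h. The mean of probe sets called the drug pathway, G2/M, SRF and YAP, BCL2 and DNA repair lists at 2 h and BCL2 at 24 h, and the dim filter histone genes at 8 h and 24 h. Over the repeats without 1 array, 2326 of 2562 gene calls were kept and 236 lost, with 7 gained, and 230 of 252 list calls were kept and 22 lost, with 8 gained. The 24 h count stayed within 1.5 times of 6714 except with a 2-fold threshold or every probe set. Median centring kept the totals within 1.5 times but not their split: 62 up and 26 down at 2 h (reported 67 and 42), 444 up and 212 down at 4 h (reported 361 and 310), 2796 and 804 at 8 h (1655 and 1347), 3584 and 3050 at 24 h (3137 and 3577), 3749 and 1776 for the mean effect (2316 and 2659) 17 and 6 from 1 h to 2 h (20 and 9), 32 and 33 from 2 h to 4 h (38 and 59), 178 and 78 from 4 h to 8 h (153 and 157) and 1296 and 2283 from 8 h to 24 h (1624 and 2224). With it the median change of all genes at 8 h was 0.08374 (reported 0.003685). Signal over background limits what can be seen: changes of dim genes are compressed, and no detection calls were used here.

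Counts that moved by more than 1.5 times, as reported and then under the alternative, were as follows. Testing every probe set on its own, which tests more items, gave 11 at 1 h (reported 1), 171 at 2 h (109), 1119 at 4 h (671), 5321 at 8 h (3002), 13552 at 24 h (6714), 9350 for the mean effect (4975), 12627 for the F test (6441), 6780 from 8 h to 24 h (3848) and 6512 for DMSO 24 h against 1 h (3634). A fit of only the arrays compared, which has fewer arrays to estimate the spread, gave 0, 10, 295 and 1493 at 1, 2, 4 and 8 h, and 1, 23 and 117 for the changes from 1 h to 2 h (29), 2 h to 4 h (97) and 4 h to 8 h (310). A 2-fold threshold, which is stricter, gave 0, 8, 51, 164 and 1079 at the 5 times, 42 for the mean effect, 5, 12, 33 and 642 for the 4 changes, and 114 for DMSO. An adjusted p under 0.01 gave 53, 374 and 1880 at 2, 4 and 8 h, 19, 44 and 117 for the changes up to 8 h, and 2346 for DMSO. Adjusting over the 5 comparisons together gave 136 at 1 h and 434 at 2 h (184 up and 250 down), since the many small p-values of 24 h relax the threshold there. Of the named gene calls at the 5 times (1, 38, 64, 108 and 126), a fit of only the arrays compared kept 0, 8, 38, 83 and 121, and brightness as a covariate kept 0, 38, 56, 83 and 122. Without _x_at and _s_at probe sets, 1, 31, 49, 88 and 104 of these calls could be compared. Of them 0, 2, 2, 15 and 4 were lost. Among the losses were ATF3 at 4 h and GDF15 and IFI44 at 8 h, where another probe set stands for the gene. Brightness as a covariate gave 0 at 1 h, 1890 at 8 h and 3116 for the mean effect. At 1 h the filter on dim probe sets gave 4, leaving out _x_at and _s_at probe sets 5, trend and robust 3, array weights 2, the constant 1 gave 0 and leaving out the 3 arrays of lowest weight 2. The larger constant gave 152 from 2 h to 4 h, and leaving out _x_at and _s_at probe sets gave 192 from 4 h to 8 h. Fry called 70 list shifts instead of 42, a test that does not compare a list with other genes.

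With each array left out in turn, the count at 1 h ran from 0 (without DMSO replicate 2, MLN4924 replicate 1 or MLN4924 replicate 2) to 4 (without MLN4924 replicate 3), and was 2 without DMSO replicate 3. Where the count at 1 h was 0, limma gave an unadjusted p under 0.05 for 958 genes with the constant 1, 1073 in the fit of only the arrays compared, 1185 with brightness, and 1371, 930 and 928 without DMSO replicate 2, MLN4924 replicate 1 and MLN4924 replicate 2. At 2 h it ran from 68 (without DMSO replicate 2) to 244 (without DMSO replicate 3), with 69 without DMSO replicate 1 and 71 without MLN4924 replicate 2. Without DMSO 2 h replicates 1 and 2 together, those of highest ACTB ratio, it was 41 at 2 h, 18 from 1 h to 2 h and 39 from 2 h to 4 h. Of 58 calls of named genes in these comparisons 32 were then kept and 26 lost, and 1 array is left in the group, which is assumed to vary like the other groups. It ran from 21 to 45 (without DMSO 2 h replicate 3) for 1 h to 2 h and from 61 (without DMSO 2 h replicate 2) to 111 for 2 h to 4 h. From 4 h to 8 h it ran from 174 (without DMSO 4 h replicate 3) to 285, with 204 without DMSO 8 h replicate 1, 192 without MLN4924 4 h replicate 1 and 189 without MLN4924 8 h replicate 1. The other counts stayed within 1.5 times, with 458 to 547 at 4 h, 2429 to 2610 at 8 h, 6074 to 6269 at 24 h and 39 to 44 list shifts.

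Some results reversed. The ribosomal protein list at 4 h (reported median -0.001) was 0.219 with median centring and 0.16 as deposited. HIF1A at 8 h (reported -0.02) was 0.263 with median centring. PSMB4 at 8 h (reported -0.17) was 0.133 with median centring, 0.015 as deposited and 0.084 with the mean of its probe sets. With that mean RSRP1 was 0.007 from 1 h to 2 h (reported -0.56). For these the cause was not tested.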

Other observations

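The genes named here were picked after the results were seen, and the tests are those of the comparisons, fixed in advance. Outputs of the MAPK pathway parted at 24 h. Of 20 members 11 fell with MLN4924 and 7 rose, and the list as a whole was not called (median -0.499, adjusted p = 0.24). Those that fell include the feedback inhibitor genes SPRY2 (-2.03, adjusted p = 9.56e-17), SPRY4 (-1.56), SPRED1 (-1.3) and DUSP6 (-1.07), and the transcription factor genes ETV1 (-2.45, 4.14e-15) and ETV5 (-1.2), which growth factor signalling induces. Those that rose include MYC (2.14), MAFF (1.98), DUSP5 (1.75), EPHA2 (1.75) and FOSL1 (0.93), of which MYC and FOSL1 are also on the immediate early list.

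Genes of the melanocyte lineage fell in 8 of 20 cases and rose in 1 at 24 h (camera adjusted p = 0.0531, not called). The list was called lower with median centring (0.026), signals as deposited (0.0341) and the mean of a gene's probe sets (0.0341), and without DMSO 24 h replicate 1 (0.0484), MLN4924 24 h replicate 1 (0.0364) or MLN4924 replicate 3 (0.0492), with a range from 7.49e-10 to 0.0826 over 13 alternatives. S100B (-3.49), the endothelin receptor gene EDNRB (-1.47), RAB38, which serves pigment granule transport (-1.1), and SOX10 (-1.08) fell. The log2 change was -0.06 for MITF, the lineage's master regulator, -0.04 for the pigment enzyme gene TYR and -0.25 for the pigment granule gene PMEL, none of them called. Of 21 measured genes of senescence-associated secretion 4 rose and 8 fell at 24 h, and the list was not called (adjusted p = 0.477). Those that rose include IL6 (2.09) and VEGFA (0.8), and those that fell IGFBP5 (-4.09), IGFBP3 (-1.22) and TIMP1 (-1.19).

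Of the genes called at both 8 h and 24 h, 217 went opposite ways. IL24 changed by -1.23 at 8 h and 2.45 at 24 h (adjusted p of the difference 2.22e-15) and DKK1 by -0.63 and 1.6 (1.18e-15), each measured by 1 probe set. The secreted signal gene WNT5A changed by 1.66 and -0.32 (1.49e-10), and its other probe set by 2.49 and -0.58. The 217 rest on 1 probe set per gene, and their other probe sets were not compared.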
